A study of Homo sapiens with 4 samples.

How the data were processed

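RNA from the human leukaemia line NOMO-1 was measured on 4 expression arrays, 1 for each lentiviral construct. Per the labels, RNA was taken 48 h after selection of cells transduced at a multiplicity of infection of 1, extracted with Trizol, and 200 ng was amplified and labelled with biotin with the Ambion WT kit. The control group held a GFP virus (LEN-GFP, replicate 1) and a scrambled hairpin (SCR, replicate 2). The ZFX knock-down group held the hairpins ZFX-SH1 (replicate 1) and ZFX-SH3 (replicate 2). The replicate numbers only name the arrays, and no array repeats a construct. The p-values therefore measure the spread between constructs and arrays together, and nothing in the labels says whether the cultures were independent of each other.

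The authors deposited 1 table of 33297 probe sets, with a linear intensity per array. Affymetrix Expression Console 1.1 and RMA, a method that usually joins background correction, quantile normalization and median polish of the probes of a set, are named in the submitters' processing notes. RMA gives log2 values, and the step that turned these deposited intensities to a linear scale is not given in the sources used here. The median intensity was 184.8 for LEN-GFP, 189.8 for SCR, 189.0 for ZFX-SH1 and 186.0 for ZFX-SH3, and the lowest value of the table was 21.0. No value marks a probe set as detected or not, so a dim gene could not be told from an unexpressed one. A quantile step makes the arrays alike in overall distribution, and a change in total RNA per cell is not visible after it. RMA and the summary of many probes also compress fold changes of dim genes.

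The intensities were turned to log2 with no offset. Probe sets were named through the platform's annotation table, and the NCBI RefSeq gene table of assembly GRCh38.p14 was used for current symbols and gene types. Of the 33297 probe sets, 19460 had 1 gene symbol, 1754 had several and 12083 had none, which means that they are not named here. Of the probe sets with 1 symbol, 19429 had an Entrez gene ID in the RefSeq table, and 0 symbols needed an update. They covered 18417 genes, of which 769 had more than 1 probe set. The probe set with the highest mean log2 over the 4 arrays stood for its gene. Among the genes tested, 619 had several probe sets, and in 138 of these the probe sets differed in the sign of the difference between the groups. The 30% of genes with the lowest mean log2 over the 4 arrays (5525 genes, under a log2 value of 6.70) were left out, so 12892 genes were tested. All 4 value columns of the table were used.

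The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the 12892 genes and a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and a prior worth 2.95. Since no gene passed the threshold, the separation of the groups was described by the gap between the nearest hairpin and control arrays. The count of genes past a limit on this gap was added after the count of 0 was seen, while the use of the gap to fill places among the named genes was part of the fixed rule. A gap of 0.5 on the log2 scale was taken as the limit, and the same count was made in 100 simulated sets of 4 unchanged arrays with each gene's residual spread.

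For gene groups, 34 lists (25 pathways and 9 sets of markers of other cell types) were fixed. Of their 953 entries 862 were on the array under a single symbol, and the other entries were not analysed here. Lists with at least 5 tested genes (32 of 34) were tested with camera (limma) at a preset correlation between genes of 0.01, and again with a correlation estimated from the arrays and with fry. The T cell list and the mast cell and eosinophil list had too few tested genes. Adjustment was over the 32 lists. Single arrays were compared gene by gene with limma, each as its own group, with the pair of the other group giving the spread. These fits were added after the data were seen. A list's median between single arrays was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Concordance of the hairpins was described by the correlation, across genes, of each hairpin array minus the mean of both controls, beside 100 simulated sets of unchanged arrays.

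The genes named were chosen by a fixed rule. ZFX, PTPMT1 and IDH2 were always named. Up to 12 genes per direction past the threshold would have followed, and the places left were filled with the genes of widest gap, which did not pass. Lists were given up to 4 members with the largest difference in the direction of the list, and each comparison of 2 single arrays was given 6 genes per direction. Genes without a protein-coding symbol were passed over, which left out 1 higher gene (ADGRE4P). Groups, tests, lists, the rule for names and most of the alternatives were set before the data were examined.

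The steps were tested on 20 simulated sets of 12892 genes with the real spread, 200 of which were changed by a known amount. limma called 1.14% of genes changed by 0.5 on the log2 scale, 43.7% of those changed by 1, and 92.0% of those changed by 2. It called 0.04% of unchanged genes. A list shifted by 0.3 was called by camera in 20 of 20 sets, and other lists in 2 of 620 tests. The simulated genes were drawn independently of each other. In the real arrays the estimated correlation of the called lists ranged from -0.05 for natural killer markers to 0.73 for hypoxia genes. The low rate of false list calls in the simulated sets therefore does not carry over to the real lists. The number of arrays limits the precision. The alternatives were other variance priors, ordinary statistics without moderation, quantile normalization and median centring, other filters and other treatment of probe sets, array weights, other thresholds and set tests, separate controls for each hairpin, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.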

Results

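Gene expression was measured in NOMO-1, a human acute myeloid leukaemia line of monocytic type, after hairpins against ZFX were delivered with lentivirus. ZFX is a zinc finger transcription factor of the X chromosome with a known role in the self-renewal of blood and embryonic stem cells. The control group held 2 arrays, 1 from cells with a GFP virus (LEN-GFP) and 1 from cells with a scrambled hairpin (SCR). The knock-down group held 2 arrays, 1 for each of the hairpins SH1 and SH3. Values are deposited linear intensities of probe sets turned to log2, and 12892 genes were tested. The median intensity was between 184.8 and 189.8 on the 4 arrays. The question was which genes and gene groups differ when ZFX is reduced.

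ZFX mRNA was lower on both hairpin arrays, at 69.3% of its control level. Its log2 intensity was 10.65 on LEN-GFP and 10.66 on SCR, against 10.13 on SH1 and 10.12 on SH3. The difference was -0.53 (SE 0.10, 2 against 2 arrays), and the hairpins reached nearly the same level, 69.7% of control for SH1 and 68.9% for SH3. limma's adjusted p was 0.797 over all 12892 genes and 0.0116 over the 3 genes fixed in advance alone. Without LEN-GFP or without SCR the difference stayed at -0.54 and -0.52, and the adjusted p over the 3 genes was 0.153 and 0.166. The other 2 fixed genes, which have been linked to ZFX in leukaemia, did not pass. PTPMT1, a phosphatase of the mitochondrial membrane, differed by -0.20 (SE 0.16, adjusted p over the 3 genes 0.401), with -0.02 on SH1 and -0.38 on SH3. IDH2, the mitochondrial isocitrate dehydrogenase, differed by 0.11 (SE 0.15, adjusted p over the 3 genes 0.515), with -0.05 on SH1 and 0.26 on SH3.

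The 12 genes named as higher were those with the widest gap of both hairpin arrays above both controls. Picking extremes in this way tends to overstate their differences and understate their SE. Among them were receptors of myeloid cells and an interferon-induced enzyme. CLEC4A, a lectin receptor of myeloid cells, was 2.38-fold higher (log2 1.25, SE 0.15). OAS1, an oligoadenylate synthetase induced by interferon, was 2.51-fold higher (log2 1.32, SE 0.18). CD226, an activating adhesion receptor, was 2.48-fold higher (log2 1.31, SE 0.21). The inhibitory receptors LILRB2 and LILRB1, which bind class I molecules on other cells, differed by 0.78 (SE 0.11) and 0.77 (SE 0.12). CHI3L1, a chitinase-like protein secreted by macrophages, was 2.10-fold higher (log2 1.07), from an already high log2 level of 11.95 in the controls. SCIMP, a membrane adaptor of antigen-presenting cells, differed by 1.00 and DTX4, a ubiquitin ligase of the Deltex family, also by 1.00. The potassium channel genes KCNMB1 and KCNK10 differed by 0.96 and 0.89, KIAA0513 by 0.96, and the actin-binding TWF1 by 0.88, with 0.99 on its other probe set. None of these 12 genes passed the test over all genes (adjusted p = 0.797 for each in limma).

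The 12 genes named as lower were picked by the same rule, with the same limit on their values, and were of mixed function. FHIP2A was at 49.6% of its control level (log2 -1.01, SE 0.11), with values of 8.38 on SH1 and 8.33 on SH3 against 9.40 and 9.33 on the controls. PDGFC, a platelet-derived growth factor, differed by -1.30 (SE 0.28), and CLDN1, a tight junction protein, by -1.25 (SE 0.28). GZMA, the serine protease granzyme A of cytotoxic lymphocytes, differed by -1.05 (SE 0.24). The zinc finger genes ZNF32 and ZNF275 differed by -0.94 and -0.81, DIS3L, an exonuclease of the cytoplasmic exosome, by -0.90, and MLH3, a mismatch repair gene, by -0.89. IFT22, of the intraflagellar transport complex, differed by -0.84 and PSAT1, an enzyme of serine synthesis, by -0.83. TSPAN31, a tetraspanin, and MAPK9, a c-Jun N-terminal kinase, differed by -0.64 and -0.63. None of these 12 genes passed the test over all genes either (adjusted p = 0.797 for each in limma).

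**Figure D1:**
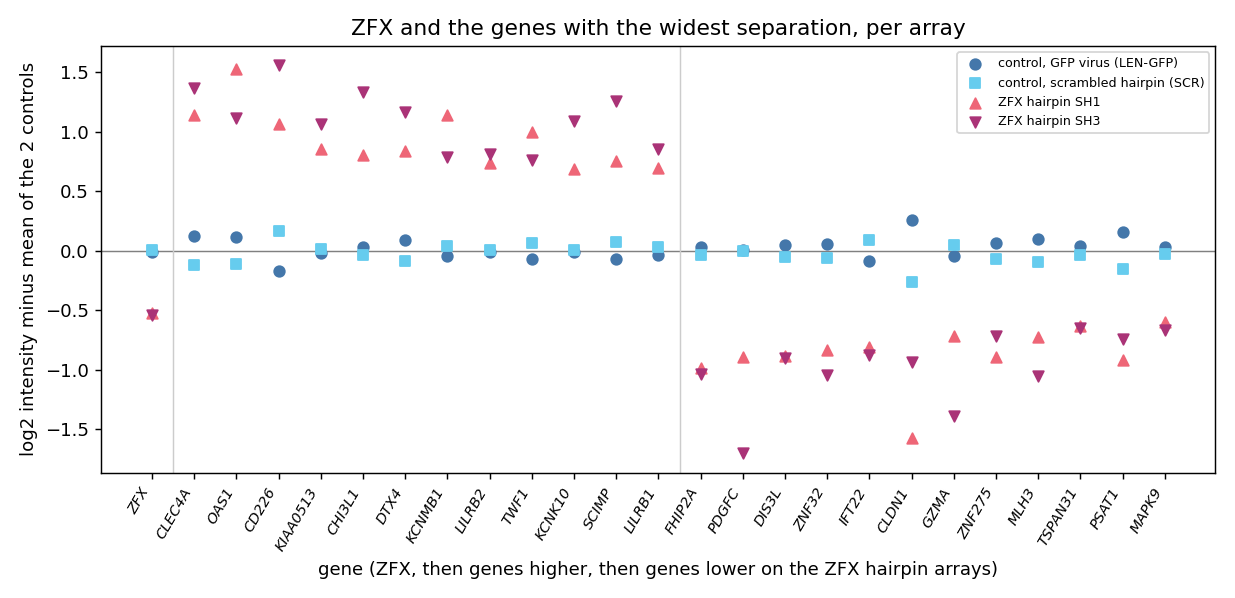
Log2 intensity of each array minus the mean of the 2 control arrays (vertical axis) for ZFX, the 12 genes named as higher and the 12 named as lower, with 1 point per array. The genes other than ZFX were chosen for a wide gap, so on them both hairpin points lie on the same side of both control points by choice. ZFX itself lies at -0.52 for SH1 and -0.54 for SH3.

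Across the 12892 genes, 0 passed an adjusted p of 0.05 in limma, with a smallest adjusted p of 0.797. At an unadjusted p under 0.05 there were 779 genes, 359 higher and 420 lower, where 645 would be reached by chance. Ordinary statistics without moderation gave 0 genes past adjustment and 686 at an unadjusted p under 0.05. Both hairpin arrays lay beyond both controls by at least 0.5 on 59 genes, 29 higher and 30 lower. Simulated unchanged arrays gave 61.9 such genes on average. The other 2 ways of splitting the 4 arrays in pairs gave 8 and 19. In limma they gave 185 and 593 genes at an unadjusted p under 0.05, so the 645 is no firm chance level for these arrays. The groups did not overlap on 37.2% of all genes, against 25.3% and 37.4% in the other splits, where chance gives 33.3%.

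Set alone against both controls, SH3 differed on far more genes than SH1. With the SH1 array left out, limma called 1698 genes, 808 higher and 890 lower. With the SH3 array left out, it called 54 genes, 22 higher and 32 lower. The lone array is assumed in these fits to vary like the control pair, whose own difference was small, and leaving out either control gave 0 genes. The calls of the 2 fits shared 20 genes, 12 higher and 8 lower, and 0 went in opposite directions. Independent lists would share 1.38 and 2.21 genes, and 20 simulated sets of unchanged arrays against the same controls shared 0.05 on average and at most 1. These simulated arrays all had the same spread, unlike the real ones, so that number is no strict bound. Part of the excess may come from the shared controls, which could not be split. Of the 20 genes, 9 were among the 12 named as higher (CD226, CHI3L1, CLEC4A, KCNK10, KCNMB1, KIAA0513, OAS1, SCIMP and TWF1) and 5 among the 12 named as lower (CLDN1, DIS3L, FHIP2A, PDGFC and ZNF275). Those genes were chosen for a wide gap of both hairpins from the same controls, so this overlap is expected from the choice. DCHS2 and HIPK3 on the higher side, and CCDC92, LRRC41 and TXNDC12 on the lower side, were also in both and are named here after their values were seen. ZFX had an adjusted p of 0.113 for SH1 and 0.0182 for SH3 in these fits.

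Endoplasmic reticulum chaperones and MYC targets were called lower by camera with the preset correlation (adjusted p 1.64e-06 and 4.05e-06). With an estimated correlation (adjusted p = 0.632 for each) and by fry (0.565 for each) neither was called. Of 19 genes for endoplasmic reticulum chaperones, 17 were lower, with a median of -0.22 (-0.19 on SH1, -0.36 on SH3), and 13 had both hairpin arrays below both controls. Examples were the co-chaperone DNAJC3 (-0.85, SE 0.33, with -0.37 on SH1 and -1.33 on SH3), the chaperone HYOU1 (-0.68, SE 0.20, with -0.90 and -0.46), XBP1, a transcription factor of the unfolded protein response (-0.47, with -0.22 on SH1 and -0.72 on SH3), and the disulfide isomerase PDIA4 (-0.41, with -0.29 and -0.53). Of 39 MYC targets and genes of ribosome biogenesis, 33 were lower, with a median of -0.22 (-0.06 on SH1, -0.32 on SH3). MYC itself differed by -0.59 (SE 0.27), the pseudouridine synthase DKC1 by -0.58 (SE 0.12), BOP1 by -0.55 and PNO1 by -0.53. Apart from DKC1 these came mostly from SH3, with -0.99, -0.89 and -0.81 for MYC, BOP1 and PNO1, against -0.20, -0.21 and -0.26 on SH1. The mean of the MYC list was -0.21, and -0.09 without SH3. No member of either list passed on its own, over all genes or adjusted over the list alone. With the preset correlation both lists were called with each array left out in turn.

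Interferon-stimulated genes and genes of monocyte and macrophage maturation were called higher by camera with the preset correlation (adjusted p = 5.44e-04 for each). With an estimated correlation (0.632 for each) and by fry (0.565 for each) neither was called. Of 27 interferon-stimulated genes, 18 were higher, with a median of 0.21, 0.23 on SH1 and 0.19 on SH3, while SCR lay below LEN-GFP by a median of -0.12. OAS1 was followed by IFI6 (0.93, SE 0.19), the chemokine CXCL10 (0.64, SE 0.27, with 0.27 on SH1 and 1.02 on SH3) and OAS2 (0.52, SE 0.16). With arrays left out OAS2 ranged from 0.33 to 0.70. Only 1 member, OAS1, passed in limma when adjusted over the list alone (adjusted p = 0.0230). Of 39 monocyte and macrophage genes, 26 were higher, with a median of 0.10 (0.06 on SH1, 0.26 on SH3), and their mean was 0.19, and 0.12 without SH3. FPR1, the formyl peptide receptor, differed by 0.92 (SE 0.58) and was higher on SH3 alone, at 1.82 against 0.03 on SH1. LILRB2 and LILRB1 passed in limma when adjusted over the list alone (smallest adjusted p = 0.0232). CSF1R, the receptor for macrophage colony-stimulating factor, differed by 0.58 (SE 0.27), with 0.96 on SH1 and 0.21 on SH3. Adjustment over a list alone makes no allowance for the 32 lists tried, so passes such as those of OAS1, LILRB2 and LILRB1 can arise by chance. With the preset correlation both lists were called with each array left out in turn.

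Camera with the preset correlation also called 5 other lists lower, and none of them with an estimated correlation (adjusted p = 0.632 for each). Among these the natural killer markers (adjusted p = 0.00434) were called with each array left out, but not with no filter on dim genes (adjusted p = 0.0670), and the other 4 lists lost their call without at least 1 array. The ATF4 integrated stress response list (29 genes, 25 lower) had a median of -0.28, with -0.39 on SH1 and -0.12 on SH3, but SCR also lay below LEN-GFP, by -0.33. Its leading members were ALDH1L2 (-1.07, SE 0.45), an enzyme of folate metabolism, and PSAT1, and the call was lost without SH1 (adjusted p = 0.142). The mean of the list was -0.28, and -0.08 without LEN-GFP (adjusted p = 0.0355), -0.48 without SCR, -0.12 without SH1 and -0.45 without SH3. ALDH1L2 was at -0.38 without LEN-GFP and at -1.75 without SCR. The list of neutrophil granule genes (15 genes, 11 lower) had a median of -0.27, led by the collagenase MMP8 (-1.16, SE 1.15) and the defensin DEFA4 (-0.99, SE 0.44, with -0.32 on SH1 and -1.66 on SH3). MMP8 was lower on SH3 alone, at -2.80 against 0.47 on SH1, and the mean of the list was -0.36 with both hairpins and -0.08 without SH3. Markers of natural killer cells (7 genes, 6 lower) had a median of -0.27, led by GZMA and KLRF1 (-0.46, with -0.28 on SH1 and -0.65 on SH3, and -0.26 without LEN-GFP). Genes of DNA replication and S phase (44 genes, 37 lower) had a median of -0.10, with CCNE1, the cyclin E gene, at -0.61 (-0.32 on SH1, -0.90 on SH3) and the chromatin assembly factor CHAF1B at -0.40. The mitochondrial ribosome (68 genes, 44 lower) had a median of -0.07 (-0.02 on SH1, -0.11 on SH3), led by MRPL33 (-0.57) and MRPL20 (-0.54). MRPL33 was lower on SH3 alone, at -1.16 against 0.03 on SH1, and MRPL20 was at -0.83 and -0.26. camera's adjusted p with the preset correlation was 1.94e-05 for ATF4, 0.00456 for replication, 0.0110 for granules and 0.0146 for the mitochondrial ribosome. Leaving out SH3 ended the granule call (adjusted p = 0.0535), leaving out LEN-GFP or SH1 ended that of replication (up to 0.101), and leaving out LEN-GFP or SH3 that of the mitochondrial ribosome (up to 0.413). With no filter on dim genes the granule list had an adjusted p of 0.0537.

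The other 6 higher lists came mainly from SH3. camera's adjusted p with the preset correlation lay between 5.44e-04 for NF-kB genes and 0.0146 for immediate early genes and cholesterol synthesis. None was called with an estimated correlation (adjusted p = 0.632 for 5 of them and 0.693 for immediate early genes). The genes named below are given as SH3 and then SH1, each minus the mean of the controls. NF-kB and inflammatory genes (25 genes, 21 higher) had a median of 0.56 on SH3 and 0.05 on SH1, with the cytokine IL1A at 2.22 and 0.03 and the chemokine CCL2 at 2.18 and -0.16. Hypoxia genes (17 genes, 15 higher) had a median of 0.49 on SH3 and -0.02 on SH1, with EGLN3, an oxygen-sensing hydroxylase, at 1.59 and 0.15 and BHLHE40 at 1.40 and -0.02. Immediate early genes (22 genes, 18 higher) had medians of 0.44 and -0.04, with DUSP1 at 1.83 and -0.63 and ETV5 at 1.13 and 0.00. Cholesterol synthesis (19 genes, 15 higher) had medians of 0.27 and 0.05, with INSIG1 at 0.65 and 0.15 and ACAT2 at 0.45 and 0.15. Glycolysis (19 genes, 17 higher) had medians of 0.21 and -0.01, with the glucose transporter SLC2A3 at 1.18 and 0.38 and the enolase ENO2 at 1.25 and 0.18. Apoptosis regulators (22 genes, 16 higher) had medians of 0.13 and 0.06, with the anti-apoptotic BCL2A1 at 0.85 and 0.42 and the pro-apoptotic BMF at 0.96 and 0.29. The controls themselves differed on some of the genes named. SCR minus LEN-GFP was -0.98 for DUSP1, -0.60 for CCL2 and -0.56 for IL1A, but 0.55 for BCL2A1 and 0.33 for SLC2A3. For the hypoxia list its median was -0.14. Without SH3 none of these 6 lists was called, with adjusted p of 0.767 for NF-kB genes, hypoxia and glycolysis, 0.460 for cholesterol, 0.413 for immediate early genes and 0.359 for apoptosis. Immediate early genes were also lost with the lowest 50% of genes left out (adjusted p = 0.0744).

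**Figure D2:**
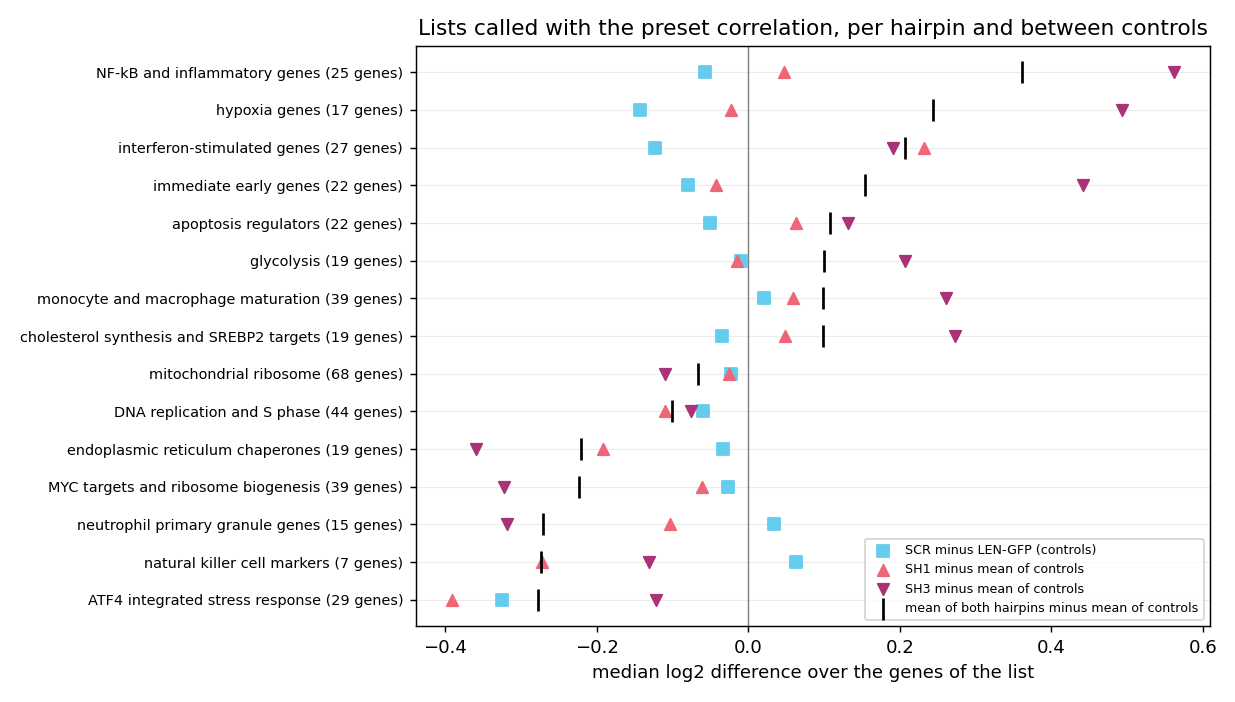
Median log2 difference over the tested genes of each of the 15 lists called with the preset correlation (horizontal axis), for SH1 and SH3 minus the mean of the controls, for the mean of both hairpins minus the mean of the controls, and for SCR minus LEN-GFP. SH1 and SH3 lie close together for interferon-stimulated genes, at 0.23 and 0.19, and far apart for hypoxia genes, at -0.02 and 0.49.

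In all, 15 of the 32 lists were called with the preset correlation, 8 higher and 7 lower, against 6 and 7 lists in the other 2 splits of the arrays. With an estimated correlation 0 lists were called, and 0 by fry. Its smallest adjusted p, 0.0701, was for megakaryocyte and platelet markers, which camera did not call. For the 15 lists that camera called, fry's adjusted p was 0.565 or higher. With 2 residual degrees of freedom these 2 tests have little power, and the simulated lists were tested with the preset correlation only. Apoptosis regulators had an estimated correlation of 0.0015, under the preset 0.01, yet camera's unadjusted p rose from 0.0050 to 0.0934. A missing call in these 2 tests therefore does not count against a list, and it does not establish one either. The 17 lists that were not called included p53 targets (median -0.05), the HOXA and MEIS1 programme of leukaemia (0.10, 20 of its 29 genes tested), stem and progenitor genes (-0.02), oxidative phosphorylation (-0.01), the tricarboxylic acid cycle (-0.0038), cytosolic ribosomal proteins (0.04) and G2 and mitosis (0.03). Lysosomal genes (0.10), NRF2 targets (0.04), cytosolic heat shock genes (0.07) and the small RNA machinery (0.02) were not called either. Nor were the markers of dendritic cells (0.07), B cells (0.03), megakaryocytes (0.05), erythroid cells (0.03), fibroblasts (0.02) and epithelium (-0.01). The median and the mean differed in sign for stem and progenitor genes (mean 0.02), epithelial markers (mean 0.03) and fibroblast markers (mean -0.0087), and camera placed each of these 3 on the higher side.

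The likeness of the hairpin arrays in direction was compared across genes. Each hairpin minus the mean of the controls gave a Pearson r of 0.267 and a Spearman rho of 0.270 across the 12892 genes, with the same sign on 59.6%. Genes are not independent replicates, and the hairpins share their controls. Unchanged simulated arrays, with the spread seen within both groups, gave an r of 0.332 (SD 0.020), the same sign on 60.9% and a covariance of 0.0210, against 0.0184 observed. That spread includes the large difference between SH3 and SH1, and shared controls alone give a positive r, so this comparison does not exclude a shared effect. The spread of the controls alone would add a covariance of 0.00805, which leaves 0.0104. Against separate controls, r was 0.0496 for SH1 minus LEN-GFP with SH3 minus SCR, and 0.246 for SH1 minus SCR with SH3 minus LEN-GFP.

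SH3 and SH1, each with 1 array, were far apart. At least a 2-fold difference was seen on 239 genes, 117 higher and 122 lower on SH3, and 8 genes differed so much between the controls. With the control pair giving the spread (1 residual degree of freedom), limma called 1095 genes, 517 higher and 578 lower on SH3. This fit, added after the data were seen, assumes that the hairpin arrays vary like the controls, and it cannot part a hairpin from its array. The metalloreductase STEAP4 was higher on SH3 by 3.23 on the log2 scale, the UDP-glucose receptor P2RY14 by 3.09, the lectin CD22 by 2.92, FHDC1 by 2.56, SPP1, which encodes osteopontin, by 2.47, and the phosphatase DUSP1 by 2.45. On the lower side were MMP8 (-3.27), TARP (-2.88), the defensin DEFB1 (-2.48), the transporter SLC29A4 (-2.44), the sialyltransferase ST8SIA6 (-2.37) and the retinol carrier RBP4 (-2.32). A dim probe set of TARP differed by 0.14. The list medians of SH3 minus SH1 were 0.67 for hypoxia genes, 0.43 for NF-kB genes, 0.43 for immediate early genes and 0.31 for ATF4 genes, each at percentile 100 of matched random lists. Neutrophil granule genes (-0.41) and MYC targets (-0.24) were at percentile 0. The random lists were drawn gene by gene, without the correlation within a real list, estimated at 0.73 for hypoxia and 0.52 for ATF4 genes. A list whose genes move together can reach either end through 1 array, so these percentiles are no test.

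**Figure D3:**
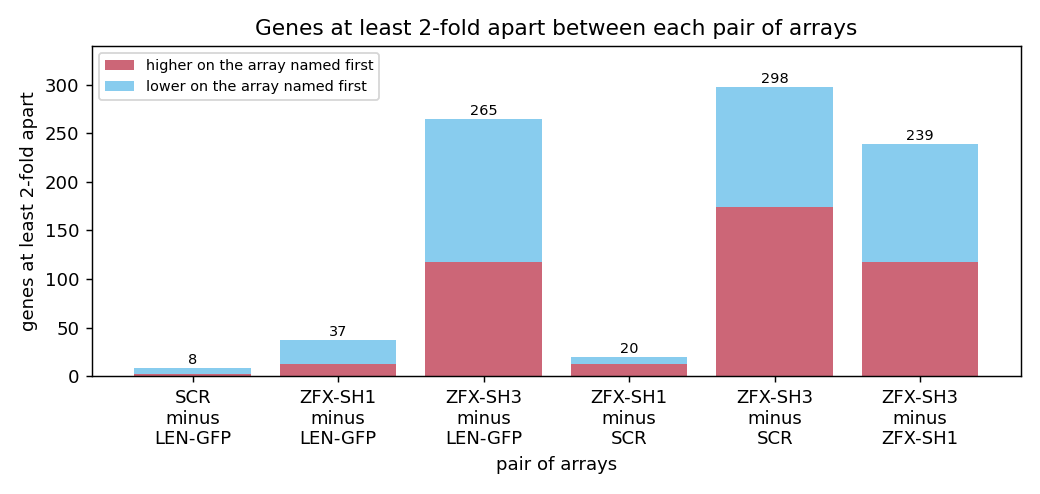
Number of tested genes at least 2-fold apart (vertical axis) for each of the 6 pairs of arrays, split by direction. The 3 pairs with SH3 hold 239 to 298 genes, and the 3 pairs without it hold 8 to 37.

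The controls lay closer together. On SCR, MMP8 was higher than on LEN-GFP by 1.55, the chemokine CXCL8 by 0.80, CYTIP by 0.71, CD177 by 0.70, SUCNR1 by 0.62 and PAQR5 by 0.60. Lower on SCR were ALDH1L2 (-1.37), RXFP1 (-1.18), CLSTN2 (-1.13), STEAP4 (-1.13), SEMA3A (-1.01) and KCNE1 (-1.0). The ATF4 list had a median of -0.33 at percentile 0 of matched random lists, interferon-stimulated genes -0.12 at percentile 0.51, and oxidative phosphorylation 0.04 at percentile 100. These random lists too were drawn without correlation between genes. With the hairpin pair giving the spread, limma called 0 genes between the controls, and 82 at an unadjusted p under 0.05. The hairpin pair was far apart, so this fit could miss differences.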

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

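The limit of 0.5 on the gap, its other limits the fits of that count and the tests between single arrays were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because the arrays of a group carry different constructs and no label pairs them across groups. The count of 0 genes past the test held under the other priors, scalings, filters, probe set rules, weights and thresholds, and ranged from 0 to 1698 when arrays were left out. ZFX ranged from -0.54 to -0.52 with arrays left out. Its call over the 3 fixed genes was lost without LEN-GFP and without SCR, where the hairpin pair alone gave the spread across genes. Genes with a gap of at least 0.5 numbered 54 to 530 higher and 48 to 620 lower with arrays left out, since 1 array is then nearest by itself. There were 46 higher with every probe set, 131 higher and 159 lower at a limit of 0.3, and 2 higher and 0 lower at a limit of 1. The lists called ranged from 8 to 15 with arrays left out, and were 0 with an estimated correlation and 0 by fry. The hairpin correlation moved to 0.0496 and 0.246 with separate controls. Endoplasmic reticulum chaperones, interferon-stimulated genes, monocyte genes and MYC targets were called under the 9 other settings (camera on ranks, scaling, filters, mean of probe sets and left-out arrays), but not with an estimated correlation (adjusted p = 0.632 for each) or by fry (0.565 for each).

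Of 760 values of named genes other than ZFX and 346 of lists, 7 gene values changed sign and 18 list values turned in the direction of the test. In 6 of these 18 the mean of the list kept its sign. Many of the gene values could not change sign, so 7 of 760 is no measure of stability. The other priors, ordinary statistics and array weights left each gene's difference as it was. The 24 genes of widest gap keep their sign with any array left out, because of how they were chosen. With arrays left out, IDH2 ranged from -0.051 to 0.26, BHLHE40 from -0.023 to 1.40, CCL2 from -0.16 to 2.18, DUSP1 from -0.63 to 1.83, MMP8 from -2.80 to 0.47 and MRPL33 from -1.16 to 0.027. The list means ranged from -0.032 to 0.65 for hypoxia genes and from -0.083 to 0.44 for immediate early genes. Lists that were not called ranged from -0.012 to 0.037 for cytosolic heat shock, -0.032 to 0.093 for epithelial markers, -0.033 to 0.13 for erythroid markers, -0.082 to 0.065 for fibroblast markers, -0.0080 to 0.10 for G2 and mitosis, -0.020 to 0.055 for stem and progenitor genes, -0.048 to 0.13 for lysosome, -0.033 to 0.11 for NRF2 targets, -0.048 to -0.023 for oxidative phosphorylation and -0.10 to -0.012 for the tricarboxylic acid cycle. With no filter on dim genes, epithelial markers had a mean of -0.014 and stem and progenitor genes of -0.017. Of the lists not called, p53 targets, G2 and mitosis, and lysosome were called in 4 values: p53 targets with no filter and without SH3, the other 2 without SH1. fry turned fibroblast markers (mean -0.0087). The cause of these turns was not tested. Signal over background is not given in the table, so dim genes have the least certain differences.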

Other observations

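The tests of a response to any hairpin RNA, of greater ZFX loss on SH3 and of a difference shared with the controls were chosen after the results were seen. Some lower genes belong to intraflagellar transport, which builds cilia, a group picked after the values were seen. IFT22, CLUAP1 (-0.54, SE 0.08), TRAF3IP1 (-0.69, SE 0.11) and KIFAP3 (-0.60, SE 0.11) were lower on both hairpin arrays, and none passed the test over all genes (limma's adjusted p 0.797 for each). The hypothesis that the whole group is lower was tested on the 15 members that had not prompted it. Their median was -0.06 (-0.12 on SH1, -0.04 on SH3), with 9 of 15 lower, at percentile 13.5 of matched random lists, which leaves the hypothesis open. On the same members SCR lay below LEN-GFP by a median of -0.10. Among them 5 lay below both controls on both hairpins, such as IFT52 (-0.71, SE 0.15) and IFT43 (-0.46, SE 0.11), and 2 above, IFT80 (0.16) and IFT122 (0.49, SE 0.21). Over all genes tested the groups did not overlap on 37.2%.

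Outside the genes compared, 13837 probe sets (unnamed or with several symbols) were searched for a gap of at least 1 between the groups. There were 0 higher and 0 lower. The genes left out as dim were not part of this search.

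The 59 genes on which both hairpin arrays lay at least 0.5 beyond both controls were weighed against chance. Probe set intensity is argued against as the cause, since 54.2% of the genes lay in the lower part of the genes by mean log2, a nearly even share. Unchanged arrays with each gene's residual spread gave 61.9 such genes on average and up to 82, so their number may come from the spread between arrays alone, although that spread includes the difference between the hairpins. Of the 3 splits of the arrays, 1 gave as many genes, the real one, and the highest other gave 19, but 3 splits are too few for a share under 0.05. An effect of ZFX loss on some of the 59 genes stays open.

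The higher interferon-stimulated genes were weighed against 2 other sources. A response to any hairpin RNA would have raised the list on SCR above LEN-GFP. The list was lower there instead, by a median of -0.12, but with 1 array per construct this source cannot be told apart. Cells of another type cannot be told apart either: the highest of their marker lists reached percentile 87.8 of matched random lists, but each list held only 5 to 7 tested genes that went both ways. A response to the sequence of each ZFX hairpin, to the amount of virus, or to ZFX loss stays open, and with 1 array per hairpin the design cannot part them.

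The distance of SH3 from the other arrays was weighed last. Greater loss of ZFX is argued against only at the level of mRNA, since ZFX differed by -0.015 between SH3 and SH1, where the median gene differed by 0.161 in size. This rests on 1 probe set and 1 array per hairpin. ZFX protein was not measured, so greater loss of the protein on SH3 stays open. An intensity-dependent scale left in these values is argued against too. After cyclic loess normalization 235 genes were still at least 2-fold apart between the hairpins, against 239 before and 7 for the controls. The arrays were already alike in overall distribution, so this step had little left to change. It cannot speak to the quality of the SH3 array. A state difference that also parts the controls cannot be told apart, since SH3 minus SH1 correlated with LEN-GFP minus SCR across genes at r = 0.217 (rho 0.210), between the bounds set for it. An effect of SH3 on other transcripts, or of the culture it came from, was not tested.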
